A study of Homo sapiens with 6 samples.

How the data were processed

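Poly-A RNA was selected with oligo-dT beads from total RNA of CAL27 cells and sequenced for 6 libraries, 3 untreated and 3 from cells given 10 mM lactate for 24 h. Groups were taken from the treatment given in the sample labels. Per the submitters' processing notes the tools were fastp, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 with the human build hg38, which is GRCh38. The role of each tool, the annotation release and whether strand was used in counting are not given in the sources used here. The form of lactate (acid or salt) and the pH of the medium are not given either.

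The deposited table holds FPKM, a fragment count scaled to gene length and library total, for 31368 genes in the 6 libraries. 8154 genes carried no symbol in the table, and symbols for these were looked up in the reference gene table, which held 31067 of the identifiers. 30228 identifiers were found in GENCODE 29, which gave coordinates, biotypes and GC content of the longest transcript. 210 entries were transcribed regions without an annotated gene and held 0.138% to 0.160% of FPKM per library. The values of low genes were small whole multiples of a constant per library and gene. Whole reads were therefore recovered from each gene's 6 values with a common gene length, to within 0.003 reads in all 6 libraries for 30840 genes (98.3%). The recovered denominators followed median-ratio size factors with a spread of 0.0239%, and sums of recovered reads with a spread of 6.20%. Recovered reads came to 103% ± 0.625 of the denominators in untreated and 97.9% ± 0.573 in lactate libraries (exact two-sided permutation p = 0.1). The deposited values therefore appear already scaled between libraries, which the labels do not state.

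Because the unit is FPKM, the main test was limma (3.58.1, in R 4.3.3) with trended and robust variance on log2(FPKM + 1), over the 11792 genes with at least 1 FPKM in at least 3 libraries. Group was the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are lactate over untreated on the log2(FPKM + 1) scale, which understates the change of low genes. The SE beside a fold change is limma's moderated one, and ± is the SD over 3 libraries. Gene groups were 40 lists written from general knowledge; 37 had at least 5 tested members. They held 882 genes, of which 859 were in the table. The lists were tested with camera at its preset correlation of 0.01, adjusted over the 37 lists, and beside it with camera at an estimated correlation and with fry. Library composition was compared by exact two-sided permutation tests of the difference of means. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

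Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is described as made after seeing the data. The rule named the 10 largest rises and the 10 largest falls among genes past the threshold with a symbol, a mean of at least 1 FPKM and groups that did not overlap. It also named up to 4 members with the smallest p in the direction of each list that passed camera. In the glycolysis, hypoxia, lactate transport and lactylation lists the 4 with the smallest p in either direction were taken. The 5 genes with the smallest p in each direction were added, as were LDHA, LDHB, SLC16A1, SLC16A3, HCAR1, EP300 and AARS1. Since 11 of the 20 largest changes were in small RNAs or pseudogenes, the 10 largest in each direction among protein-coding genes were named too, a choice made after seeing the data. Some genes that the rule names are not reported here.

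The alternatives tried were quantile normalization, median centring of each library, limma without a variance trend, no filter on low values, and a filter at 5 FPKM. The others were a pseudocount of 0.1, protein-coding genes only, a minimum fold of 1.2, an adjusted p under 0.01, the replicate number as a block, and each library left out in turn. Added after seeing the data were removal of each library's trend on GC content and gene length (natural splines with 4 degrees of freedom), scaling to the totals of recovered reads, and voom on recovered reads. Settings meant for count tables, which need read counts as deposited, did not apply. The test was tried on simulated libraries with the depths of the real ones and the same spread for all genes. That spread was the median over genes of at least 500 reads, 1.46% beyond counting noise. Genes that vary more were not simulated, so the rates may be too favourable. It found 18% of 50 genes changed 1.1-fold, 68% at 1.2-fold, 96% at 1.5-fold and 94% at 2-fold, with 11 calls among 11555 unchanged genes. In libraries simulated with a GC trend and no other change, 2353 of 11578 genes passed without the correction and 0 with it.

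For the closing section, random lists were matched gene by gene on transcript length, GC content and mean expression among 9880 protein-coding genes. Each of 10000 draws took, for every member, 1 of its 50 nearest genes. Length and GC content came from the principal transcript with the best APPRIS level, an annotation grade for main isoforms. The difference from matched lists was also taken with list members resampled with replacement in each draw, and its central 95% decided which explanations of list medians stay open. This range treats list members as independent genes and carries no spread between libraries, so it may be too narrow.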

Results

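The data are poly-A-selected RNA-seq profiles of CAL27, a human cell line derived from a squamous cell carcinoma of the tongue. 3 libraries came from untreated cells and 3 from cells kept in 10 mM lactate for 24 h. The series set out to relate lactate, and the lactylation of lysine residues for which it provides the acyl group, to gene regulation in oral squamous cell carcinoma. The chromatin profiling that belongs to the same project was not analysed here. Expression was given as FPKM for 31368 genes, and the denominators behind these values were 28287542, 25163374 and 33297625 reads in untreated replicates 1 to 3. In lactate replicates 1 to 3 they were 30957477, 32888734 and 40220226 reads. The whole reads recovered from the values summed to 25765467 (untreated replicate 2) to 39305334 (lactate replicate 3) per library. At that depth 1 FPKM in a 2 kb gene rested on 50.3 to 80.4 reads, and in a 100 nt gene on 2.52 to 4.02 reads. Across genes, log2 values correlated at a Pearson r of 0.996 to 0.997 between libraries of the same group and at 0.989 to 0.991 between libraries of different groups. No pair of libraries was as alike as resequencing of 1 library would give, since chi-square per gene within groups was 1.86 to 3.84. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

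The comparison asks which transcripts differed after 24 h of lactate. In lactate, mRNAs for cholesterol synthesis and uptake were lower as a set at camera's preset correlation, though not at an estimated one (adjusted p = 0.133). SCD, which encodes stearoyl-CoA desaturase, stood at 57.5 ± 1.2 FPKM in untreated cells and 27.6 ± 0.375 in lactate (mean ± SD, n = 3 each). ATF4, a transcription factor of the amino acid and integrated stress response, and many of its target genes were lower too, as were mRNAs for ribosome biogenesis, ribosomal proteins and the respiratory chain, again not at an estimated correlation (adjusted p = 0.133 for the ATF4 target and ribosome biogenesis lists and 0.0737 for the others). The respiratory chain list did not pass after quantile normalization either (camera adjusted p = 0.128). ARRDC4 and TXNIP, paralogous arrestin-domain genes whose transcription responds to glucose and acid, were higher. So were NDRG1, THBS1, and the lists of matrix proteases, mesenchymal genes, targets of the coactivator YAP and basal keratinocyte genes (adjusted p = 0.133 to 0.180 at an estimated correlation). Of 37 gene lists tested, 9 passed camera with its preset correlation (4 up, 5 down). With an estimated correlation 0 passed (9 at an unadjusted p under 0.05), and by fry, which tests each list on its own, 30 passed. The estimate was under the preset 0.01 for the respiratory chain (-0.0105), ribosome biogenesis (-0.00784) and matrix protease (-0.0158) lists. It was also under 0.01 for the mesenchymal (-0.0276), YAP (-0.0121) and basal keratinocyte (-0.0134) lists, so a higher correlation did not raise p there. For the ribosomal protein (0.0280), ATF4 target (0.0577) and cholesterol (0.0245) lists it was over 0.01. Most changes were small. Of 11792 genes tested, 6914 (58.6%) passed limma at a Benjamini-Hochberg adjusted p under 0.05, with 3265 higher and 3649 lower in lactate. With libraries scaled to the totals of their reads instead, a choice made after seeing the data, 4179 rose and 2575 fell. The median absolute log2 fold change of the 6914 genes was 0.23, and 58.7% of them changed by less than 0.25. 85 genes changed at least 1.5-fold (31 up, 54 down) and 8 at least 2-fold (4 up, 4 down) on the log2(FPKM + 1) scale. The count of 8 became 40 with a pseudocount of 0.1 and 66 with voom on recovered reads, and leaving out 1 library moved its split to as far as 8 up and 2 down or 2 up and 7 down. Against a minimum fold of 1.2, 429 genes passed (187 up, 242 down). In 6856 of the 6914 genes the groups' values did not overlap, which their selection by a test on the same values makes likely. Among all tested genes the groups did not overlap in 65.5%, where chance gives 10%. Among protein-coding genes 3100 rose and 3091 fell of 9885 tested.

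**Figure D1:**
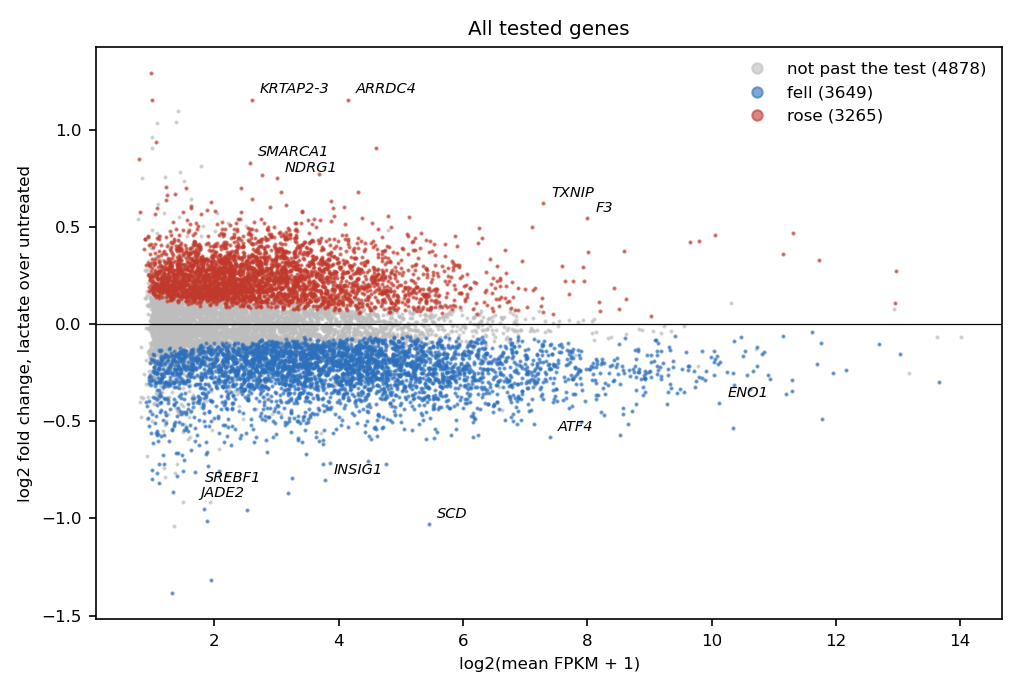
Log2 fold change (lactate over untreated, y axis) against log2(mean FPKM + 1) over the 6 libraries (x axis) for the 11792 genes tested, with genes past the adjusted p threshold coloured and some named genes labelled. The 6914 changed genes lie mostly close to 0, and SCD at -1.03 and ARRDC4 at 1.16 stand at the edges of the protein-coding genes.

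Of the 8 genes that changed at least 2-fold on the log2(FPKM + 1) scale, 3 encode proteins. ARRDC4 (ENSG00000140450, chromosome 15, 97960698 to 97973838 in GRCh38) rose from 9.92 ± 0.265 to 23.3 ± 0.379 FPKM (log2 fold change 1.16, SE 0.028, adjusted p = 3.35e-06). KRTAP2-3, a keratin-associated protein gene with close paralogs, rose from 2.76 ± 0.478 to 7.34 ± 0.215 FPKM (log2 fold change 1.16). SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834) fell by 1.03 on the log2 scale (SE 0.023, adjusted p = 3.35e-06). The other 5 were short or pseudogene transcripts with few reads: a pair of Y RNA genes, MIR3929, RNU6-785P and an unprocessed pseudogene, with 3 to 17 reads per library on average. By the fixed rule for the largest changes with non-overlapping groups, RPSAP9, SNORA2B, RPS26P15 and UBE2WP1 also stood among the 10 largest falls. SNORD127, MIR3153, MT-TL2, RNU6-510P and RNVU1-27 stood among the 10 largest rises. These 9 had on average 3.17 (SNORD127) to 99.7 (RPSAP9) reads per library. The libraries were poly-A selected, so reads at the small RNA genes named here need not come from the mature small RNAs. Their source was not tested. RNU6-510P lay at the threshold (adjusted p = 0.0492) and no longer passed with untreated replicate 1 or 3 or any lactate replicate left out (0.0714 to 0.135). It was also lost with quantile normalization, median centring, no variance trend, no filter on low values, a pseudocount of 0.1, the replicate block or the GC and length trend removed (0.0530 to 0.115). MT-TL2 no longer passed without untreated replicate 2 or 3 or lactate replicate 2 (0.0572 to 0.0785) or with no filter on low values (0.0560), and MIR3929 without untreated replicate 1 or 3 or lactate replicate 3 (0.0534 to 0.0586) or with the replicate block (0.0669). Among protein-coding genes, the falls next to SCD were JADE2 (10.8 to 5.46 FPKM, log2 fold change -0.87), INSIG1 (-0.80), SREBF1 (-0.79), FST, which encodes follistatin (-0.72), and RBM3, which encodes a cold-inducible RNA-binding protein (-0.71). PRKAR1B (-0.61), ATF5 (-0.61), TOE1 (-0.60) and SURF2 (-0.59) completed the 10. The rises next to ARRDC4 and KRTAP2-3 were SMARCA1, a chromatin remodelling ATPase (3.26 to 6.58 FPKM, log2 fold change 0.83, ratio of means 2.02), NDRG1 (0.75), the receptor gene NOTCH3 (0.70, ratio of means 2.14), SMURF2 (0.68), TMPRSS15 (0.68), MYH10 (0.65), PLOD2 (0.63) and ELOVL4 (0.63). The genes with the smallest p included the rising TXNIP (122 ± 0.992 to 189 ± 2.04 FPKM, log2 fold change 0.62), the tissue factor gene F3 (207 to 303), the glucosylceramide synthase gene UGCG (27.3 to 40.5) and THBS1, which encodes thrombospondin (62.7 to 88.7). On the falling side they included APEX1, a DNA repair endonuclease gene (475 to 332 FPKM, log2 fold change -0.51), EIF5A (438 to 318), ENO1 (1270 to 959) and NOB1 (88.9 to 59.6). Each of these 8 lay on the same side in all 3 lactate libraries against all 3 untreated libraries, which their choice by smallest p makes likely.

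**Figure D2:**
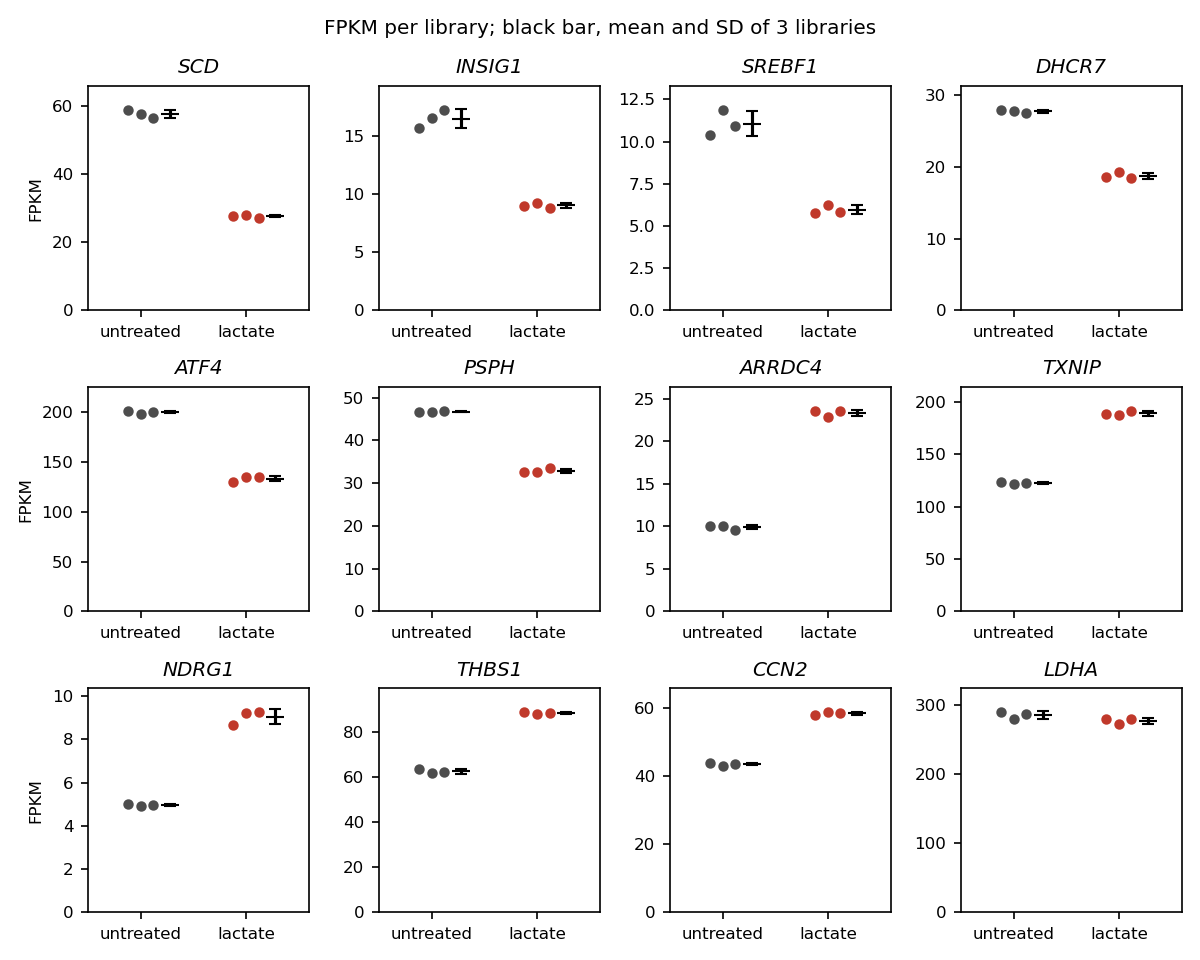
FPKM in each of the 6 libraries (y axis, a scale starting at 0 in each panel) for 12 genes named in the text, with points for libraries and black bars for group means ± SD (n = 3 each). SCD, INSIG1, SREBF1, DHCR7, ATF4 and PSPH lie lower in every lactate library than in any untreated one, and LDHA overlaps between groups.

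Cholesterol genes moved down as a set with individual exceptions. Of 25 tested genes of cholesterol synthesis and uptake, 18 fell and 1 rose (19 and 1 when adjusted over the list alone), with a median log2 fold change of -0.30 (camera adjusted p = 3.00e-05; adjusted p = 0.133 with an estimated correlation). INSIG1, the sterol-regulated retention factor of SREBP processing (ENSG00000186480, chromosome 7, 155297776 to 155310235), went from 16.5 ± 0.787 to 9.03 ± 0.231 FPKM. DHCR7, which encodes the last enzyme of a route to cholesterol, went from 27.8 ± 0.227 to 18.8 ± 0.403 FPKM (log2 fold change -0.54), and ACAT2 changed by -0.38. Among 15 tested genes of fatty acid synthesis, 8 fell and 4 rose (8 and 5 when adjusted over the list alone), and this list did not pass camera (median -0.17, adjusted p = 0.387). In that list SCD and SREBF1 fell most. SREBF1, the gene of the transcription factor SREBP1 (ENSG00000072310, chromosome 17, 17810399 to 17837002), fell from 11.1 ± 0.748 to 5.96 ± 0.263 FPKM. Its exons overlap those of RAI1 on the opposite strand by 556 nt (gene length 8234 nt). Other named genes overlap more for their length. On the opposite strand they include NDUFA1 (341 nt, length 842 nt), NOB1 (429 nt, length 2101 nt) and TOE1 (552 nt, length 2358 nt). ACAT2 overlaps an untested gene by 1458 nt on the opposite strand (length 5278 nt). LDHB overlaps an untested gene by 997 nt on the same strand (length 2983 nt). After removal of each library's trend on GC content and gene length, chosen after seeing the data, the cholesterol list had a median of -0.24 and passed with an estimated correlation (adjusted p = 0.0408).

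Genes of the amino acid response formed the list with the lowest median of the 37 tested, close to the cholesterol list, which was the lower of the pair after quantile normalization (-0.25 against -0.21). Of its 23 tested members, 19 fell and 1 rose (20 and 1 when adjusted over the list alone), with a median log2 fold change of -0.31 (camera adjusted p = 2.42e-07; adjusted p = 0.133 with an estimated correlation). ATF4 itself (ENSG00000128272, chromosome 22, 39519695 to 39522685) went from 200 ± 1.31 to 133 ± 2.54 FPKM (log2 fold change -0.58, adjusted p = 5.69e-06). PSPH, which encodes the last enzyme of serine synthesis, went from 46.7 ± 0.146 to 32.9 ± 0.489 FPKM. The glutamine transporter gene SLC1A5 went from 136 ± 1.08 to 99.4 ± 1.09 FPKM, and ATF5 from 6.48 ± 0.119 to 3.92 ± 0.115 FPKM; the exons of ATF5 overlap those of NUP62 by 626 nt. The member that rose was ALDH1L2, a mitochondrial folate enzyme gene (1.39 to 1.72 FPKM), named after its values were seen. With the GC and length trend removed the median was -0.30 (adjusted p = 0.0408 with an estimated correlation).

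Transcripts for making ribosomes and for the respiratory chain were lower. Among 26 tested MYC targets and ribosome biogenesis genes, 17 fell and 5 rose (18 and 5 when adjusted over the list alone; median -0.21, camera adjusted p = 0.00520; adjusted p = 0.133 with an estimated correlation). The examples with the smallest p were the snoRNP protein gene NOP56 (85.2 ± 0.719 to 56.6 ± 0.976 FPKM, log2 fold change -0.58), NOB1 (-0.57), MRTO4 (-0.49) and FBL, the fibrillarin gene (-0.32). Restricting the test to genes of at least 5 FPKM left this list, with 23 members and a median of -0.22, at an adjusted p of 0.0510. Of 75 cytosolic ribosomal protein genes, 66 fell, also when adjusted over the list alone, and 9 did not pass (median -0.22, camera adjusted p = 2.34e-17; adjusted p = 0.0737 with an estimated correlation). RPLP0 changed by -0.34, RPLP1 by -0.33 and RPL19 by -0.28; such genes have processed pseudogenes that can share their reads. Processed pseudogenes leaned lower, with 245 lower and 48 higher of 605 tested (median -0.15), but so did antisense transcripts (57 lower and 15 higher of 255) and lincRNAs (69 lower and 32 higher of 249), and the classes were not tested against each other. Of 36 nuclear-encoded respiratory chain genes, 29 fell and 2 rose, also when adjusted over the list alone (median -0.16, camera adjusted p = 3.62e-06; adjusted p = 0.0737 with an estimated correlation). ATP5F1B, a subunit gene of ATP synthase, went from 779 ± 9.17 to 609 ± 3.54 FPKM, ATP5MC1 changed by -0.33, NDUFA1 by -0.22 and COX4I1 by -0.21. Quantile normalization brought the median of the respiratory chain list to -0.049 (12 fallen and 5 risen, camera adjusted p = 0.128) and that of the ribosomal protein list to -0.047 (27 fallen and 7 risen, camera adjusted p = 0.0184). That of the ribosome biogenesis list became -0.13 after quantile normalization (16 fallen and 7 risen, camera adjusted p = 0.0444) and -0.14 with read totals (15 fallen and 7 risen). With read totals the respiratory chain median was -0.087 (21 fallen and 2 risen) and the ribosomal protein median -0.15 (63 fallen and 3 risen), and both lists passed. After quantile normalization RPL19 (adjusted p = 0.107), NDUFA1 (0.0889) and COX4I1 (0.242) did not pass. With the GC and length trend removed, the medians of the ribosome biogenesis, ribosomal protein and respiratory chain lists were -0.16, -0.16 and -0.14, with adjusted p of 0.0546, 0.0121 and 0.0545 at an estimated correlation. NDUFA1 did not pass (adjusted p = 0.204). The 13 mitochondrially encoded protein genes did not move as a set (3 rose, 4 fell, adjusted p = 0.541).

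Fold change followed GC content and gene length across genes, which are not independent replicates. Over 9881 protein-coding genes, Spearman rho was -0.48 with GC content and 0.32 with length, and both together accounted for 29.7% of the variance. In 5 classes of equal size from the lowest to the highest GC content the median log2 fold changes were 0.16, 0.11, -0.050, -0.12 and -0.093. In 5 such classes from the shortest to the longest genes they were -0.11, -0.046, 0.0023, 0.054 and 0.098. The length slope per doubling differed by at most 0.00235 between libraries of the same group and by 0.0440 to 0.0475 between groups. The GC slope per 10 percentage points differed by at most 0.0441 within groups and by 0.0548 to 0.132 between them. The gene lists differ in these properties. Median GC content and length were 48.1% GC and 3252 nt for ribosomal protein genes, 47.9% GC and 2664 nt for respiratory chain genes, 50.5% GC and 5197 nt for cholesterol genes, 56.7% GC and 4040 nt for the amino acid response list and 51.3% GC and 4153 nt for ribosome biogenesis. For the 4 lists that passed as higher they were 48.6% GC and 6113 nt (matrix proteases), 50.6% GC and 5213 nt (mesenchymal), 51.5% GC and 5613 nt (YAP) and 56.1% GC and 6766 nt (basal keratinocyte). Lists that did not pass include short ones with more risen than fallen members, such as NF-kB targets (50.1% GC and 2239 nt), and long ones with more fallen members, such as glycolysis (53.8% GC and 5978 nt) and fatty acid synthesis (48.7% GC and 6134 nt). With the trend removed from each library, 5661 genes passed (2675 up, 2986 down), of which 4512 were among the 6914 and 475 of the 6914 had the opposite sign. The number of lists that passed camera went from 9 to 16, and from 0 to 3 with an estimated correlation.

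**Figure D3:**
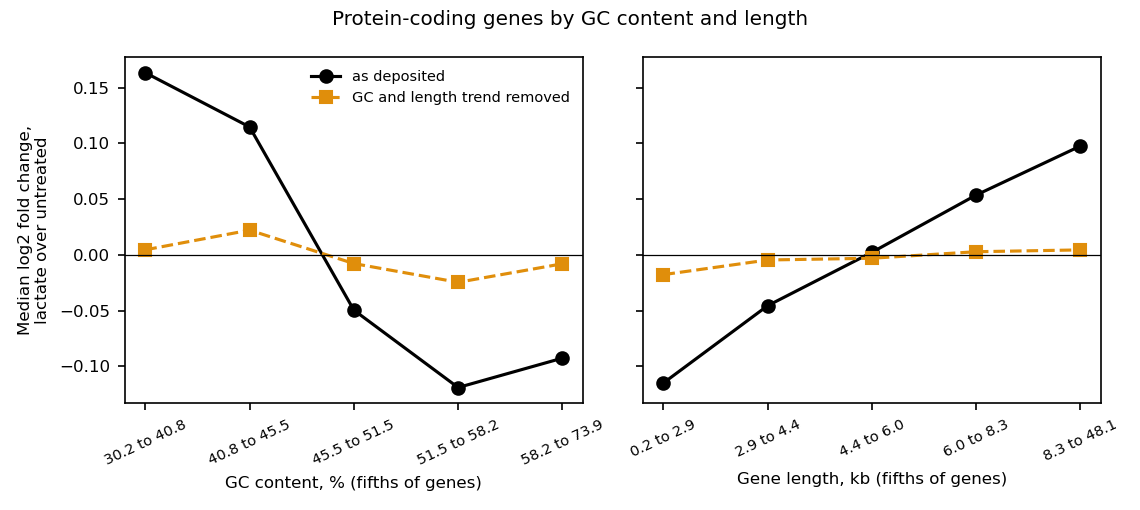
Median log2 fold change (y axis) of protein-coding genes in 5 classes of equal size by GC content (left) and by gene length (right), as deposited and after removal of each library's trend. As deposited, the medians run from 0.16 in the lowest to -0.093 in the highest class of GC content and from -0.11 to 0.098 from the shortest to the longest class.

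The lists of matrix proteases, mesenchymal genes, YAP targets and basal keratinocyte genes were higher. In the list of matrix proteases and the plasminogen system 11 of 17 tested genes rose and 2 fell (11 and 3 when adjusted over the list alone; median 0.14, camera adjusted p = 0.00501; adjusted p = 0.133 with an estimated correlation). Its leading members include an inhibitor gene as well as proteases. TIMP2, a metalloproteinase inhibitor gene, went from 4.46 ± 0.0216 to 6.95 ± 0.121 FPKM. The protease genes ADAMTS1 and ADAM9 changed by 0.50 and 0.43. In the mesenchymal list 9 of 14 tested genes rose and 2 fell, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.00920; adjusted p = 0.138 with an estimated correlation). Its examples were the integrin gene ITGB6 (0.49) and the fibronectin gene FN1 (0.35). Of the YAP and TEAD targets 12 of 17 rose and 3 fell, also when adjusted over the list alone (median 0.22, camera adjusted p = 0.00920; adjusted p = 0.138 with an estimated correlation). F3 changed by 0.55, CCN2 by 0.42 (43.6 ± 0.423 to 58.5 ± 0.497 FPKM), NT5E by 0.30 and CCN1 by 0.29. Basal keratinocyte genes rose in 10 of 16 cases and fell in 3, also when adjusted over the list alone (median 0.14, camera adjusted p = 0.0274; adjusted p = 0.180 with an estimated correlation). The integrin gene ITGA6 changed by 0.47, the laminin gene LAMA3 by 0.43 and EGFR by 0.43. Some genes stand in more than 1 of these lists. With the GC and length trend removed the medians of the matrix protease, mesenchymal, YAP and basal lists were 0.18, 0.22, 0.21 and 0.15. In the same order they were 0.20, 0.20, 0.25 and 0.29 after quantile normalization and 0.21, 0.23, 0.27 and 0.21 with read totals. Basal keratinocyte genes gave 11 risen and 2 fallen after quantile normalization, and 12 and 3 with read totals.

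**Figure D4:**
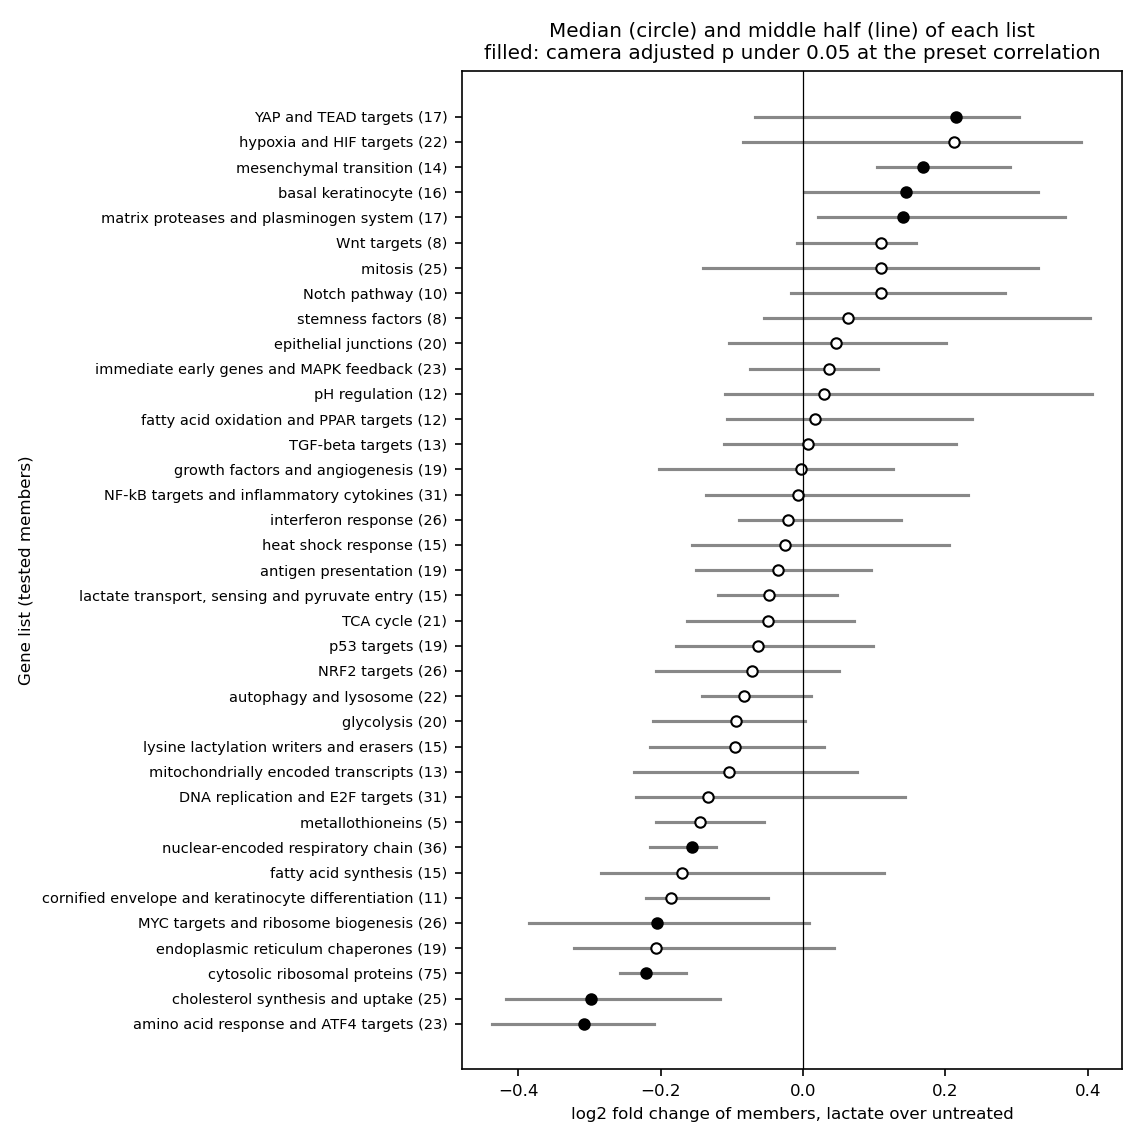
Median log2 fold change (x axis, points) and the interquartile range of members (bars) for the 37 gene lists tested (y axis), with filled points for lists past camera at an adjusted p under 0.05. The amino acid response list lies lowest at -0.31 and the YAP and TEAD list highest among filled points at 0.22.

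Lactate handling and glycolysis did not pass as sets. LDHA, which encodes the lactate dehydrogenase subunit favouring lactate production, stood at 285 ± 5.49 FPKM untreated and 277 ± 4.58 in lactate (log2 fold change -0.042, adjusted p = 0.118). The call for LDHA depended on the processing. It passed as lower after median centring (-0.063, adjusted p = 0.0342), with the GC and length trend removed (-0.12, adjusted p = 0.000406), with the replicate block (adjusted p = 0.0150) and with voom on recovered reads (adjusted p = 0.0154), and as higher after quantile normalization (0.14, adjusted p = 0.000533). LDHB fell from 25.8 ± 0.343 to 24.2 ± 0.347 FPKM (log2 fold change -0.088, adjusted p = 0.0129), and did not pass after quantile normalization (0.421), with read totals (0.491) or with the GC and length trend removed (0.0989). The monocarboxylate transporter genes SLC16A1 (37.0 and 36.3 FPKM, adjusted p = 0.324) and SLC16A3 (8.91 and 8.66 FPKM, adjusted p = 0.479) did not pass. SLC16A1 passed as higher after quantile normalization (0.066, adjusted p = 0.0347) and as lower with the GC and length trend removed (-0.12, adjusted p = 0.00108). HCAR1, the lactate receptor gene, had mean values of 0.00630 and 0.00226 FPKM and was not tested. In the list of lactate transport, sensing and pyruvate entry 4 of 15 tested genes rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.461). After quantile normalization 5 rose and 4 fell, with read totals 4 rose and 3 fell, and with the GC and length trend removed 0 rose and 6 fell. PDK1 (0.29) and EMB (0.22) rose, while MPC1, a subunit gene of the mitochondrial pyruvate carrier (-0.26), and PDHA1 (-0.18) fell. With the GC and length trend removed PDK1 (adjusted p = 0.0825) and EMB (0.187) did not pass. Of 20 glycolysis genes 11 fell and 4 rose, also when adjusted over the list alone (median -0.094, camera adjusted p = 0.0513). Glycolysis passed camera with untreated replicate 2 left out (adjusted p = 0.0346) and with the replicate block (0.0484). Its median shrank to -0.014 after quantile normalization (6 fallen and 5 risen, adjusted p = 0.844) and to -0.027 with read totals (9 fallen and 4 risen, adjusted p = 0.171). ENO1, PKM, GAPDH and TPI1 changed by -0.40, -0.30, -0.28 and -0.28, and TPI1 did not pass after quantile normalization (adjusted p = 0.121). Hypoxia and HIF targets were mixed, with 12 of 22 higher and 5 lower, also when adjusted over the list alone (median 0.21, camera adjusted p = 0.0834; adjusted p = 0.321 with an estimated correlation). With the GC and length trend removed the hypoxia list had a median of 0.096 and passed camera (adjusted p = 0.0112), but not with an estimated correlation (adjusted p = 0.178). With read totals its median was 0.31. NDRG1 went from 4.97 ± 0.0501 to 9.06 ± 0.334 FPKM and P4HA1 changed by 0.60, whereas STC2, which also stands in the amino acid response list, changed by -0.38.

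Genes reported to add or remove lysine lactylation showed no common direction. Of 15 tested, 3 rose and 6 fell (3 and 7 when adjusted over the list alone; camera adjusted p = 0.272). With read totals 3 rose and 4 fell, and after quantile normalization 3 and 8. AARS1, the alanyl-tRNA synthetase gene, fell from 78.3 ± 1.06 to 64.4 ± 0.152 FPKM (log2 fold change -0.28), KAT2A changed by -0.40 and HDAC1 by -0.26, while HDAC2 rose by 0.30. EP300, an acetyltransferase gene, rose from 2.59 ± 0.0828 to 2.99 ± 0.156 FPKM (log2 fold change 0.15, adjusted p = 0.0172), and no longer passed with no filter on low values (adjusted p = 0.0559), without lactate replicate 2 (adjusted p = 0.0546) or without untreated replicate 2 (0.0516).

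The remaining lists did not pass camera. Counts of risen and fallen among tested genes were 4 and 10 of 19 for endoplasmic reticulum chaperones (adjusted p = 0.149), 4 and 1 of 10 for the Notch pathway (0.149) and 8 and 18 of 31 for DNA replication and E2F targets (0.176). For mitosis they were 13 and 9 of 25 (0.219), for epithelial junctions 8 and 5 of 20 (0.225), and for NRF2 targets 3 and 14 of 26 (0.249). Of 8 Wnt targets 4 rose and 4 did not pass (0.225). Autophagy and lysosome genes gave 5 and 11 of 22 (0.272), stemness factors 4 and 2 of 8 (0.272), and cornified envelope genes 1 and 4 of 11 (0.272). TGF-beta targets gave 6 and 3 of 13 (0.389), the TCA cycle 4 and 10 of 21 (0.404), pH regulation 5 and 3 of 12 (0.404) and fatty acid oxidation 5 and 4 of 12 (0.468). Metallothioneins gave 1 and 2 of 5 (0.572), immediate early genes 7 and 6 of 23 (0.601), p53 targets 4 and 8 of 19 (0.675), antigen presentation 4 and 6 of 19 (0.725) and growth factors 4 and 6 of 19 (0.908). NF-kB targets gave 13 and 8 of 31 (0.469), the interferon response 8 and 8 of 26 (0.863) and the heat shock response 5 and 6 of 15 (0.960); in these 3 the median and the mean differ in sign. When adjusted over the list alone, each of these counts was the same or higher by 1. With the GC and length trend removed, the lists of endoplasmic reticulum chaperones (0.00773), the Notch pathway (0.0145), epithelial junctions (0.0374), Wnt targets (0.0315), NF-kB targets (0.0315) and fatty acid synthesis (0.0377) passed at the camera adjusted p given, and their adjusted p was 0.154 with an estimated correlation.

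Markers of other cell types stayed low. Fibroblast markers had no gene above the filter, with COL1A1 highest at 0.399 FPKM untreated and 0.431 in lactate. Of leukocyte and endothelial markers 1 each was tested, CSF1R at 1.51 and 1.24 FPKM and CDH5 at 1.22 and 0.992 FPKM, against 119 and 135 for the epithelial junction gene CLDN1. The share of FPKM from mitochondrially encoded protein genes was 20.5% ± 0.857 untreated and 20.5% ± 1.11 in lactate (exact two-sided permutation p = 1). Genes not annotated as protein coding held 23.8% ± 0.135 untreated and 23.3% ± 0.195 in lactate (exact two-sided permutation p = 0.1). The sum of FPKM was 435764 ± 5707 untreated and 402389 ± 5863 in lactate (exact two-sided permutation p = 0.1), and the 20 most abundant genes held 29.7% ± 0.704 untreated and 30.3% ± 0.906 in lactate (exact two-sided permutation p = 0.5). Genes above 0 numbered 26104 ± 516 untreated and 26576 ± 487 in lactate (exact two-sided permutation p = 0.4), and genes at 1 FPKM or more 11722 ± 10.0 untreated and 11712 ± 10.0 in lactate (exact two-sided permutation p = 0.3). With 3 libraries against 3, 0.1 is the smallest p these tests allow.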

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

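The alternatives based on GC content and length, read totals and voom on recovered reads were chosen only after the results were seen, and the others were planned. The count of 6914 changed genes stayed between 4741 and 7377 under the alternatives except the minimum fold of 1.2, which by construction asks for larger changes and left 429 genes, and was 5967 to 6432 with each library left out in turn. The 8 genes changed at least 2-fold became 3 with a filter at 5 FPKM, 3 among protein-coding genes, 4 against a minimum fold of 1.2 and 5 at an adjusted p under 0.01, where fewer genes are tested or the bar is higher. They became 40 with a pseudocount of 0.1 and 66 with voom on recovered reads, scales on which low genes are shrunk less. With each library left out in turn they were 7 to 10. The split of these few genes by direction was not stable: the 4 up and 4 down became 8 and 2 without untreated replicate 1, 2 and 7 without lactate replicate 1, 2 and 6 without lactate replicate 2, and 6 and 2 with read totals. The 9 gene lists became 0 with an estimated correlation, 30 with fry and 16 with the GC and length correction, and were 9 to 10 with each library left out.

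The sign of LDHA reversed with quantile normalization (0.14) and with read totals (0.028), that of SLC16A1 with quantile normalization (0.066) and read totals (0.040), and that of SLC16A3 with read totals (0.027). Scaling to read totals applies a single factor per library, so it raises all fold changes nearly alike, and values as close to 0 as the main ones (-0.042 for LDHA, -0.028 for SLC16A1, -0.036 for SLC16A3) turn positive. The cause of the reversals with quantile normalization was not tested. Of the 87 genes the rule named, the minimum fold of 1.2 ended 28 calls, quantile normalization 6 and the GC and length correction 5. Each left-out library ended 1 to 3 calls. Genes of at least 1 FPKM rest on at least 50.3 reads in a 2 kb gene but on as few as 2.52 in a 100 nt gene, so the values of small RNAs are the least precise. Median-ratio or no scaling of raw counts, a negative binomial model and voom on deposited counts were not run, since the deposited values are FPKM.

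With the replicate block, in which libraries that share a replicate number are paired, 7039 genes passed, 9 of them changed at least 2-fold, and 10 lists passed (6 down, glycolysis among them at an adjusted p of 0.0484). The numbers showed no pairing: deviations from group means of same-numbered libraries correlated across genes at 0.053, 0.067 and -0.0038, all under the limit of 0.1 fixed for pairing.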

Other observations

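The tests below were chosen only after the results were seen, except those on mRNAs with a 5' terminal oligopyrimidine tract and on proteasome subunits, whose outcomes were stated before their values were computed.

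Several lists held members that moved in opposite directions, most of them lists that did not pass camera. The members named here were chosen after their values were seen. Among hypoxia and HIF targets CA9 (log2 fold change 0.48), BNIP3L (0.47), ERO1A (0.39) and LOXL2 (0.38) rose with NDRG1 and P4HA1. VEGFA (-0.39), DDIT4 (-0.27) and the glucose transporter gene SLC2A1 (-0.17) fell. Within glycolysis the aldolase gene ALDOC (0.52) and the enolase gene ENO2 (0.44) rose while ENO1, the abundant paralog of ENO2, fell. In fatty acid synthesis FASN fell (-0.47), whereas ELOVL7 (0.38), ME1 (0.30) and ACSL1 (0.29) rose. Among basal keratinocyte genes, a list that passed, KRT14 rose (0.34) while its partner keratin KRT5 fell (-0.39). Proteasome subunit genes, a list added after seeing the data, were mostly lower, with 18 of 29 fallen and 4 risen (median -0.22).

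Against random lists matched on transcript length, GC content and expression, many medians lay outside the central 95% of draws. Lists not detailed here did too, such as the Notch pathway and NF-kB targets. The draws treat genes as independent, so lying outside does not by itself set a list apart. The hypoxia list had a median of 0.21 against -0.13 to 0.073 in matched lists, the YAP and TEAD list 0.22 against -0.16 to 0.050, and the mesenchymal list 0.17 against -0.15 to 0.088. The basal keratinocyte list had 0.14 against -0.16 to 0.059, and immediate early genes 0.036 against -0.21 to -0.033. Fatty acid synthesis lay below its range (-0.17 against -0.074 to 0.16), as did DNA replication and E2F targets (-0.13 against -0.11 to 0.052). The matrix protease list lay above its range (0.14 against -0.15 to 0.096). With list members resampled as well, the central 95% of the difference from matched lists held 0 for matrix proteases (-0.0019 to 0.46). It also held 0 for hypoxia, fatty acid synthesis, DNA replication, the Notch pathway and NF-kB targets. Glycolysis (-0.094 against -0.24 to -0.060) lay inside. The first version of this test matched on transcripts of the highest APPRIS level alone, which covered from 43.8% of a list's members, and was replaced after its outcome was seen. In that version the fatty acid list lay inside its range (0.052 against -0.071 to 0.23), and the other lists named here kept their side of it. Its resampled difference held 0 for the mesenchymal (-0.020 to 0.40) and basal keratinocyte lists (-0.12 to 0.56). In the later version these were 0.069 to 0.37 and 0.021 to 0.42. For matrix proteases the first version did not hold 0 (0.045 to 0.49).

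Most tested genes passed, by small changes that follow GC content and length. The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 6914 genes, and the highest other split gave 0 by limma (178 at an unadjusted p under 0.05). Every other split mixes the groups, so the difference between groups enters its spread. Its count of 0 therefore cannot show what chance alone would give. The trend, in the form removed here, is argued against as the whole cause by the 5661 genes that passed once it was removed. A simulated GC trend left 0, but it was linear in the GC content that the correction used and had no length trend. It therefore cannot speak for a trend of another form or on transcript length, which stays open. Open too is whether a difference in library preparation or RNA quality between the groups' libraries may have made the trend. Each library belongs to a single group and the labels give no batch. The length slope per doubling was 0.0053 (SE 0.0037) in genes that are not protein coding and 0.046 (SE 0.0021) in protein-coding genes, and the GC slopes per 10 percentage points were -0.077 and -0.093, which does not separate these from an effect of lactate.

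Ribosomal protein and respiratory chain transcripts were lower, though neither list passed at an estimated correlation (adjusted p = 0.0737 for both). Their fall may reflect that they are short and abundant, since genes matched on transcript length, GC content and expression fell about as far: the ribosomal protein median of -0.22 lay above the 2.5th percentile of matched lists, -0.23, and the respiratory chain median of -0.16 above -0.21. With members resampled, the difference from matched lists had a central 95% of -0.074 to 0.013 and -0.092 to 0.050, which holds 0 and not the whole fall. Quantile normalization, which removes shifts tied to abundance rank, took the medians to -0.047 and -0.049. The trend on GC content and gene length, in the form removed here, is argued against as the whole cause. After its removal 64 of 75 ribosomal protein genes and 22 of 36 respiratory chain genes fell. The medians were -0.16 (SD 0.11) and -0.14 (SD 0.12), and both lists passed camera. With an estimated correlation only the ribosomal protein list passed (adjusted p = 0.0121, and 0.0545 for the respiratory chain). That correction does not take out expression level. It used the gene length recovered from the values, with medians of 3252 nt for ribosomal protein and 2664 nt for respiratory chain genes. Their principal transcripts had medians of 1041 and 1088 nt, so part of a trend on transcript length may remain. A second candidate explanation, lower levels of mRNAs with a 5' terminal oligopyrimidine tract, stays open: 16 such mRNAs that encode no ribosomal protein had a median of 0.0040, inside -0.16 to 0.12 in matched lists, but 7 fell and 6 rose. Those that fell include the abundant EEF1A1 and EEF2. With members resampled, the difference from matched lists had a central 95% of -0.28 to 0.24, too wide to decide. That criterion was added after the median, which met the bound stated against this explanation, was seen. With transcripts of the highest APPRIS level, which 12 of the 16 have, the median was -0.11, inside -0.21 to 0.11.

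Cholesterol, ATF4 target and ribosome biogenesis transcripts were lower, though none of these lists passed at an estimated correlation (adjusted p = 0.133 for each). The medians of -0.30, -0.31 and -0.21 lay below the 2.5th percentiles of -0.12, -0.22 and -0.16 in matched lists. With members resampled, the difference from matched lists had a central 95% of -0.40 to -0.11 (cholesterol), -0.33 to -0.075 (ATF4 targets) and -0.30 to 0.050 (ribosome biogenesis), or -0.44 to -0.083, -0.32 to -0.029 and -0.34 to 0.15 with transcripts of the highest APPRIS level. With members treated as independent genes, transcript length, GC content and expression level are therefore argued against as the whole cause for the cholesterol and ATF4 target lists. They stay open for ribosome biogenesis. These ranges ignore members that move together and carry no spread between libraries, so they may be too narrow. Scaling of the libraries was weighed by this same difference, since a factor per library moves matched genes alike. It had no separate test, so its outcome is the same, under the same limits. With read totals the cholesterol, ATF4 target and ribosome biogenesis lists each still passed camera at the preset correlation (adjusted p = 8.54e-06, 7.70e-08 and 0.00532). Resampling was added after the medians were seen. A first version of the scaling test, on medians with read totals, was dropped after its outcome was seen, because that scaling shifts all genes by a fixed amount too small to decide. A hypothesis that would join these groups is lower activity of the kinase complex mTORC1, and it stays open: proteasome subunits had a median of -0.22, at percentile 1.59 of matched lists, or 2.64 with transcripts of the highest APPRIS level, and the autophagy and lysosome list had -0.082, inside -0.17 to -0.0077, with 11 members lower and 5 higher. The bound stated beforehand for proteasome subunits was a median below the 2.5th percentile. It was met in the later version of the matching but not in the first, on transcripts of the highest APPRIS level. With members resampled, the difference from matched lists held 0 for both the proteasome and the autophagy and lysosome list (-0.18 to 0.11 and -0.097 to 0.12). A difference in library preparation cannot be told apart from lactate here either, so no biological cause is assigned.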
